A study of Mus musculus with 10 samples.

How the data were processed

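Total RNA from sorted splenic cDC1s, the conventional dendritic cells that carry Xcr1 and Clec9a, was measured on 10 Affymetrix Mouse Gene 1.0 ST arrays: 3 WT, 3 Zeb2 KO, 2 Nfil3 Zeb2 DKO and 2 Zeb2 Id2 DKO. Per the labels, spleens were digested with collagenase B and DNase I, filtered and freed of red cells before cDC1s were sorted. The gate of the sort is not given in the sources used here. RNA was extracted on columns, amplified with the NuGen Ovation Pico kit and labelled with biotin. Per the submitters' processing notes, the authors processed the arrays in Affymetrix Expression Console with RMA. The deposited values are linear RMA intensities, normalized by the authors, between 5.05 and 16019, and log2 of these intensities was taken for every analysis below. The annotation used by the authors is not given in the sources used here. No pair of arrays was identical, and all 10 arrays were used.

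Of 28853 probe sets, 21789 named 1 gene, 1621 named several and 5443 named none. Gene identifiers of 21698 of the 21789 probe sets were matched to the reference gene table (GRCm38.p6, used for names and for the order of genes along chromosomes only), which changed 0 symbols. Where a gene had more than 1 probe set (999 genes), the set with the highest mean over all 10 arrays was used, which left 19938 genes. The genes' probe sets can disagree: for Adgrl2 the log2 fold change between Zeb2 Id2 DKO and WT was 2.51 with the probe set used and 1.18 with the mean of its probe sets. No gene was filtered out by level.

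Median intensity per array was 79.3 to 80.0 in WT, 76.3 to 82.9 in Zeb2 KO, 80.9 to 81.6 in Nfil3 Zeb2 DKO and 77.4 to 79.0 in Zeb2 Id2 DKO. Correlations between arrays of a group were 0.994 to 0.997 in WT, 0.986 to 0.996 in Zeb2 KO, 0.997 in Nfil3 Zeb2 DKO and 0.997 in Zeb2 Id2 DKO. The number of arrays per genotype limits precision: the median 95% confidence interval of a log2 fold change reached 0.22 to 0.26 to either side of the estimate.

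Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with a mean per genotype was fitted to all 10 arrays (6 residual degrees of freedom), and variances were moderated with empirical Bayes (prior degrees of freedom 4.47). Each genotype was compared with every other, which gave 6 comparisons. P-values were adjusted within each comparison by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Levels are means with standard deviations of log2 intensity, and brackets hold 95% confidence intervals of log2 fold changes. All p-values in the text are limma model values or come from limma's gene set tests.

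Genes named in the text were chosen by a rule: the 3 targeted genes; a panel of Irf8, Batf3, Xcr1, Clec9a, Cd8a, Itgae, Irf4, Tcf3, Tcf4, Tcf12, Spib and Siglech; and the 10 largest rises and 10 largest falls among changed genes whose arrays did not overlap. Predicted genes, small non-coding RNAs, olfactory and vomeronasal receptors, immunoglobulin and T cell receptor segments and sex-linked genes were left out of that last part. Where fewer than 10 genes changed in a direction all were named, and where fewer than 5 changed in all, the 5 genes with the smallest p in each direction were added as values only. Up to 4 members of each list, those with the smallest p, were added.

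Changes of 19 gene lists were tested: cDC1 identity, cDC2, pDC (plasmacytoid dendritic cell), E proteins and ID proteins, dendritic cell transcription factors, monocyte, red pulp macrophage, neutrophil, B cell, T cell, NK cell, erythroid, MHC class I presentation, MHC class II presentation, dendritic cell maturation, interferon-stimulated, cell cycle, immediate early and stress, and Toll-like receptors and adaptors. A further list of 4 sex-linked genes served as a check, and 0 of its members changed in any comparison. Lists were tested with camera of limma at a preset correlation of 0.01 and adjusted over the 19 lists. Each was tested again with a correlation estimated from the data, and with fry. Beside the number of members called over all genes, the number with p-values adjusted over the list alone is given.

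Calls shared by comparisons were counted against the number expected for independent comparisons (the product of both counts over all genes). They were also set against 100 simulated data sets with the same arrays and no effect, because these comparisons share arrays. In each simulation as many genes as were called per direction were taken by p, as almost none passed the threshold there. Simulations without effect, also with each array left out, were used for the correlation between the 2 effects of a further loss.

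The test was checked on simulated data for each comparison, with 200 changed genes in each of 5 runs. Between 86.6% and 92.0% of changed genes were recovered at 2-fold and 98.6% to 99.6% at 4-fold, and 3.82% to 6.29% of calls were false. With 200 changed genes the threshold is easier to pass, so these rates do not hold where few genes were called. Lcn2, 8.42-fold higher in Zeb2 KO than in WT, was not called (adjusted p = 0.107), while Ngp (8.06-fold) was. When the cell cycle list was shifted by 0.5 log2 in simulated data, 1 of 19 lists was called. Genes were simulated as independent, so this check does not cover lists whose members vary together, as those of the neutrophil list did.

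Alternatives were a shift of each array to the same median, cyclic loess, quantile normalization again, removal of genes below the 40th percentile of level, the mean of a gene's probe sets, every probe set, eBayes with a trend or robust, array weights, only the 2 groups compared, replicate number as a block, a test against a 1.2-fold change (treat) and each array left out. After the data had been seen, the removal of both WT replicate 1 and Zeb2 KO replicate 3 was added, and so were lists without the targeted genes they hold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.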

Results

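Gene expression of splenic cDC1s was compared among WT (n = 3), Zeb2 KO (n = 3), Nfil3 Zeb2 DKO (n = 2) and Zeb2 Id2 DKO (n = 2) arrays. The groups, comparisons, gene lists and the rule for named genes were set before the data were examined. The labels do not say whether replicates come from separate animals, so the p-values measure only the spread between these samples. Arrays were left out 1 at a time unless both are named, and values of a gene list with an array left out are camera results at the preset correlation.

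Nfil3 and Id2 were low in the arrays labelled as lacking them, and Zeb2 was not. Nfil3, a basic leucine zipper repressor, stood at 6.20 and 7.09 log2 in the Nfil3 Zeb2 DKO arrays against 9.98, 10.77 and 10.68 in WT, a 14.3-fold fall (log2 -3.84 [-4.43 to -3.25], adjusted p = 0.000622). In Zeb2 KO (10.13, 10.12 and 10.41) and Zeb2 Id2 DKO (10.21 and 10.28) it lay near the WT level. Id2, an inhibitor of E protein DNA binding, stood at 5.01 and 4.98 in the Zeb2 Id2 DKO arrays against 10.15, 10.32 and 10.43 in WT, a 39.6-fold fall (log2 -5.31 [-5.58 to -5.04], adjusted p = 6.58e-09). Its levels were 10.08, 9.89 and 10.29 in Zeb2 KO and 10.50 and 10.40 in Nfil3 Zeb2 DKO. Zeb2, a zinc finger repressor, stood at 6.0, 5.93 and 6.30 in WT, at percentile 41.7 of all genes. It stood at 6.10, 6.27 and 5.40 in the arrays labelled Zeb2 KO, at 6.46 and 6.24 in Nfil3 Zeb2 DKO and at 6.78 and 6.82 in Zeb2 Id2 DKO (log2 fold change against WT -0.16, adjusted p = 0.929; 0.27, adjusted p = 1.0; and 0.72, adjusted p = 0.184). The Zeb2 probe set may lie outside the deleted part, or read too low in WT to fall much. Its level then checks nothing about the deletion.

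**Figure D1:**
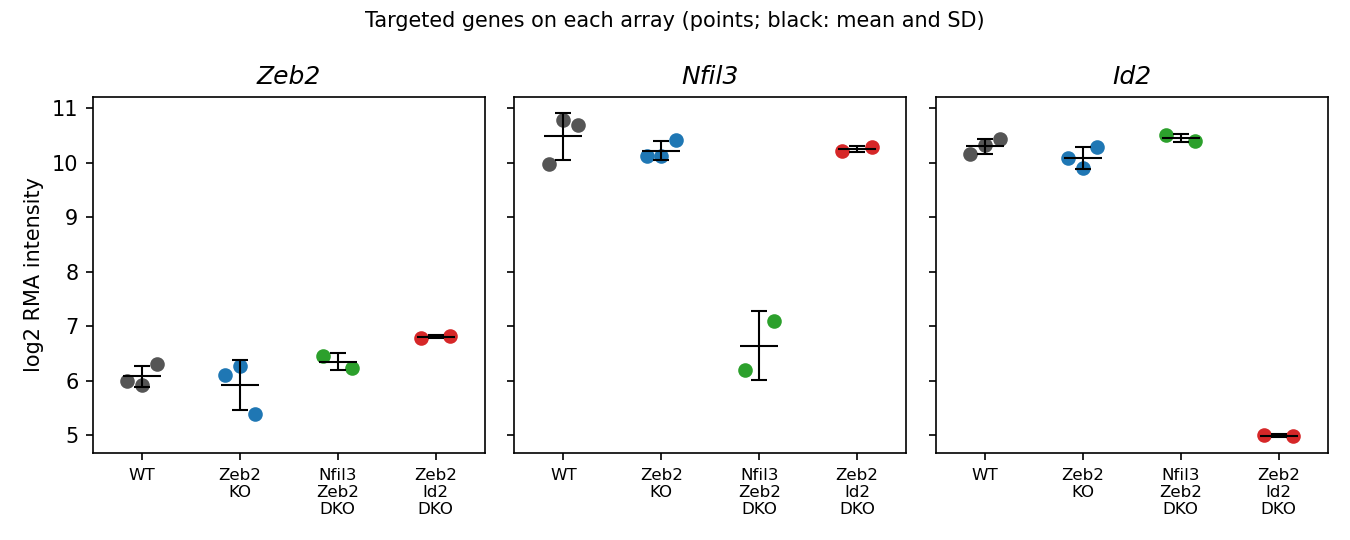
Log2 RMA intensity of Zeb2, Nfil3 and Id2 in each array (points) by genotype, with group means and standard deviations in black. Nfil3 was 14.3-fold lower in Nfil3 Zeb2 DKO and Id2 39.6-fold lower in Zeb2 Id2 DKO than in WT, while Zeb2 levels overlapped between WT and Zeb2 KO.

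In WT, Irf8, the lineage-defining transcription factor, lay at percentile 99.7 of all genes, the dead-cell receptor Clec9a at 99.2, the chemokine receptor Xcr1 at 98.8 and Batf3 at 94.9. Against WT, Xcr1 had log2 fold changes of 0.06 [-0.17 to 0.28] in Zeb2 KO, 0.00 [-0.26 to 0.26] in Nfil3 Zeb2 DKO and -0.16 [-0.41 to 0.10] in Zeb2 Id2 DKO. Values for Irf8 were 0.15 [-0.01 to 0.31], -0.05 [-0.23 to 0.13] and 0.10 [-0.08 to 0.28]. Clec9a had -0.16 [-0.34 to 0.02], -0.02 [-0.23 to 0.18] and 0.01 [-0.20 to 0.21], and Batf3 0.06 [-0.19 to 0.32], 0.12 [-0.16 to 0.41] and -0.05 [-0.34 to 0.23]. None of these 4 genes passed the test in any comparison.

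Between the Zeb2 Id2 DKO and WT arrays, 286 genes were differentially expressed: 175 up-regulated and 111 down-regulated, 69 and 35 of them by at least 2-fold. Apart from Id2, the changes that no left-out array ended included rises of Ngp, a neutrophil granule protein (11.50 ± 0.96 against 8.55 ± 0.17, 7.74-fold, adjusted p = 0.0048), and Carmil1, a regulator of actin filament capping (10.30 ± 0.13 against 7.53 ± 0.11, 6.80-fold, log2 2.76 [2.42 to 3.11], adjusted p = 1.84e-05). Plet1 rose 6.14-fold (9.22 ± 1.08 against 6.60 ± 0.09, adjusted p = 0.00695), the adhesion receptor gene Adgrl2 5.70-fold (8.88 ± 0.05 against 6.37 ± 0.22, adjusted p = 4.29e-06) and Lrrc4c 5.20-fold (5.91 ± 0.32 against 3.53 ± 0.02, adjusted p = 1.84e-05). With the mean of its probe sets, the log2 fold change of Adgrl2 was 1.18 in place of 2.51, and it was likewise 1.28 in place of 2.76 against Nfil3 Zeb2 DKO. Falls included Apol7c (8.36 ± 0.87 against 11.14 ± 0.15, 6.83-fold, log2 -2.77 [-3.43 to -2.11], adjusted p = 0.0016), Adgrl3, a relative of Adgrl2 (5.32 ± 0.01 against 7.80 ± 0.41, 5.58-fold, adjusted p = 0.000147), Adam22 (3.56-fold, adjusted p = 0.000147) and Cpne8 (3.20-fold, adjusted p = 0.00157). Icos, best known as a T cell costimulatory receptor, fell 3.13-fold (6.32 ± 0.26 against 7.96 ± 0.09, adjusted p = 0.0018).

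Other large changes between Zeb2 Id2 DKO and WT were lost when certain arrays were left out. Gp2 fell 8.51-fold (6.84 ± 0.10 against 9.93 ± 0.44, adjusted p = 0.033) and Gclc, which encodes the catalytic subunit of the first enzyme of glutathione synthesis, 3.55-fold (adjusted p = 0.0308). Both calls were lost with any WT, Nfil3 Zeb2 DKO or Zeb2 Id2 DKO array left out (adjusted p up to 0.268 and 0.263). Xlr fell 4.82-fold (adjusted p = 0.00836, and up to 0.110 without either Zeb2 Id2 DKO array). Klra5, a Ly49 family receptor gene, fell 3.69-fold (adjusted p = 0.00653, and 0.0860 without Zeb2 Id2 DKO replicate 1). Over all genes, 2028 had an unadjusted p under 0.05 against 997 expected by chance. The arrays of both groups did not overlap in any of the 286 called genes, which calling by p favours. The count moved to 136 and 120 without WT replicate 2 or 3 and 760 without Zeb2 KO replicate 3. It was 1104 without both WT replicate 1 and Zeb2 KO replicate 3.

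**Figure D2:**
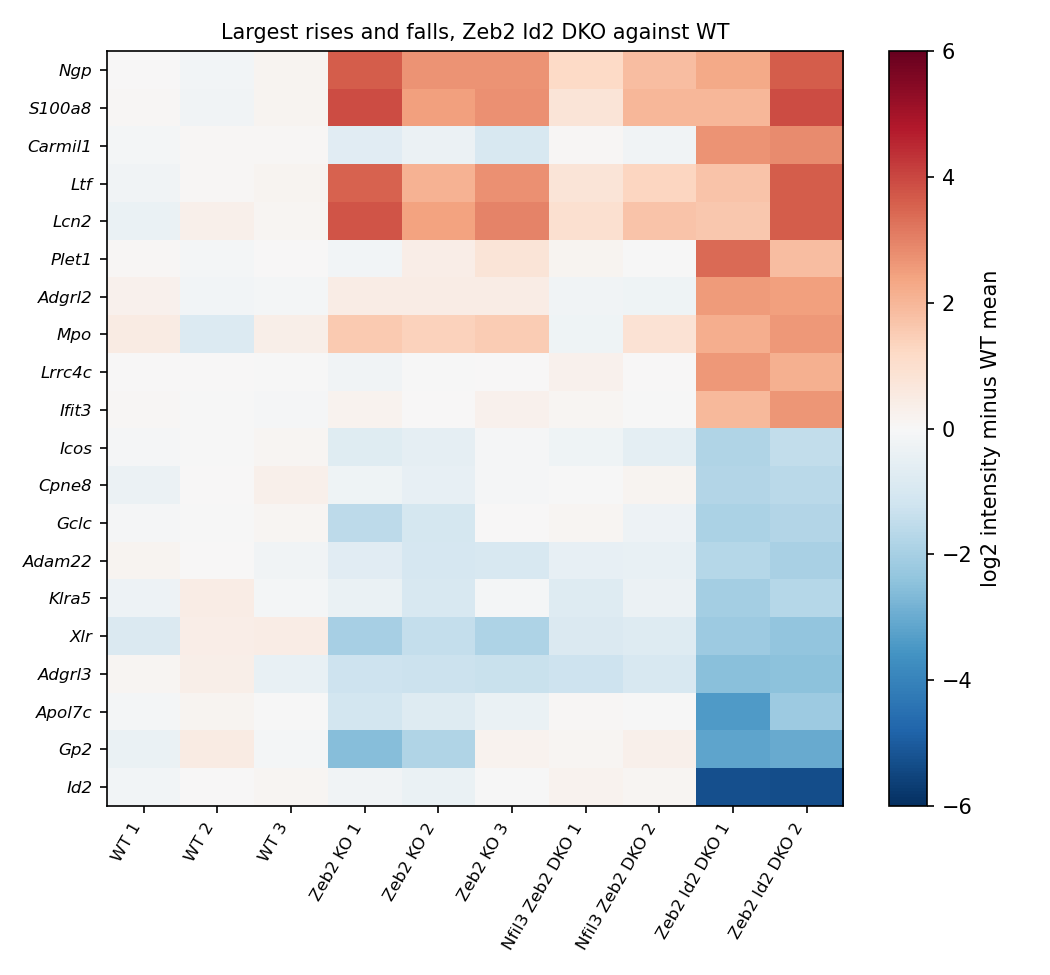
Heat map of log2 intensity minus the WT mean in all 10 arrays (columns) for the 10 largest rises and 10 largest falls between Zeb2 Id2 DKO and WT (lines). Carmil1 (log2 2.76) and Adgrl2 (2.51) were higher and Adgrl3 (-2.48) lower in both Zeb2 Id2 DKO arrays, and Ngp was also higher in the Zeb2 KO arrays.

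Interferon-stimulated genes rose in the Zeb2 Id2 DKO arrays. Of 25 measured members 14 rose and none fell against WT (22 rose when adjusted over the list alone), all 25 had positive values, and their median log2 fold change was 0.97. Ifit3 (8.62 ± 0.50 against 6.32 ± 0.07, 4.93-fold, adjusted p = 0.000147), Ifit2 (9.38 ± 0.54 against 7.22 ± 0.10, 4.48-fold, adjusted p = 0.000558), Ifit1 (3.77-fold, adjusted p = 0.000618) and Oasl2 (3.66-fold, adjusted p = 0.000299) led the list, and no left-out array ended their calls. The list was higher by camera (adjusted p = 7.48e-39, and adjusted p = 0.0718 with an estimated correlation). Its mean over members lay 0.82 and 1.31 above the WT mean in Zeb2 Id2 DKO replicates 1 and 2, at 0.21, 0.06 and -0.02 in Zeb2 KO, and at -0.20 and -0.03 in Nfil3 Zeb2 DKO. In both Zeb2 Id2 DKO arrays the neutrophil list stood 0.93 and 1.92 and the erythroid list 0.85 and 0.69 above the WT mean.

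Siglech, a surface receptor typical of plasmacytoid dendritic cells, rose in the Zeb2 Id2 DKO arrays (7.99 ± 0.12 against 6.31 ± 0.31 in WT, 3.19-fold, log2 1.67 [1.27 to 2.07], adjusted p = 0.00164). Of 30 pDC list members 4 rose and none fell (8 and 2 when adjusted over the list alone): Siglech, Bst2 (log2 0.98, adjusted p = 0.034), Cd300c (0.90, adjusted p = 0.0383) and Upb1 (0.50, adjusted p = 0.0311). Calls for Bst2, Cd300c and Upb1 were lost with any WT or Nfil3 Zeb2 DKO array or Zeb2 Id2 DKO replicate 2 left out, and for Bst2 and Cd300c also without replicate 1 (adjusted p up to 0.295, 0.399 and 0.332). The pDC list was higher by camera (median log2 fold change 0.00, mean 0.11, adjusted p = 0.0151, and adjusted p = 0.149 with an estimated correlation), and not without WT replicate 3 (0.0564) or Zeb2 Id2 DKO replicate 1 (0.0610). Among E proteins, the partners of Id2, Tcf3 had a log2 fold change of 0.02, Tcf4 of -0.01 and Tcf12 of 0.14, and Spib had -0.17, and none passed. Of the 7 E and ID protein genes only the target Id2 fell, and the other 6 did not pass as a list (median -0.01, adjusted p = 0.670).

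Within cDC1 identity, 1 of 32 genes rose and 2 fell in Zeb2 Id2 DKO against WT (2 and 5 when adjusted over the list alone). Besides Id2, Cadm1, an adhesion molecule of cDC1s, fell 1.83-fold (10.37 ± 0.12 against 11.24 ± 0.03, adjusted p = 0.00225), and Fkbp1b rose (log2 0.86, adjusted p = 0.0142). The Fkbp1b call was lost without WT replicate 2 or 3 or either Zeb2 Id2 DKO array (adjusted p up to 0.182). Cd8a had a log2 fold change of -0.52 (adjusted p = 0.0936) and the integrin gene Itgae 0.56 (adjusted p = 0.291). Without the targeted Id2 the cDC1 list did not pass (median 0.05, mean -0.02, camera direction up, adjusted p = 0.568; with Id2 mean -0.18, direction down, adjusted p = 0.785). Among 33 dendritic cell transcription factors Cebpa rose (log2 0.79, adjusted p = 0.0128). That call was lost without WT replicate 2 or 3 or either Zeb2 Id2 DKO array (adjusted p up to 0.180). When adjusted over the list alone 6 of these factors rose and 3 fell. Without Nfil3 and Zeb2 the list (median -0.01, mean 0.07, camera direction up) did not pass (adjusted p = 0.114). It came under 0.05, down to 0.0426, without WT replicate 1 or Zeb2 Id2 DKO replicate 1.

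Genes of dendritic cell maturation lay lower in Zeb2 Id2 DKO than in WT. Of 26 members 3 fell and none rose (9 fell when adjusted over the list alone): Apol7c, Il12b, the cytokine subunit that directs type 1 responses (2.08-fold, log2 -1.06, adjusted p = 0.0112), and the costimulatory ligand Cd80 (log2 -0.54, adjusted p = 0.0257). The calls of Il12b and Cd80 were lost without WT replicate 3 or either Zeb2 Id2 DKO array, and of Cd80 also without WT replicate 2 (adjusted p up to 0.132 and 0.269). The list was lower by camera (median log2 fold change -0.40, adjusted p = 3.47e-13, and adjusted p = 0.149 with an estimated correlation). Rtn1 fell in the cDC2 list (log2 -0.98, adjusted p = 0.00695, and up to 0.0928 without either Zeb2 Id2 DKO array), where 1 of 25 members fell and none rose (5 and 1 when adjusted over the list alone). That list was lower by camera (median -0.13, adjusted p = 0.00265, and adjusted p = 0.215 with an estimated correlation). This list's adjusted p was 0.0711 without Zeb2 Id2 DKO replicate 1.

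Neutrophil genes were higher in Zeb2 Id2 DKO than in WT: 7 of 17 members rose and none fell (12 rose when adjusted over the list alone). Ngp rose as above, S100a8 7.73-fold (10.06 ± 1.33 against 7.11 ± 0.20, adjusted p = 0.029), the iron-binding Ltf 6.32-fold (adjusted p = 0.029), Lcn2 6.20-fold (adjusted p = 0.0394) and the granule enzyme gene Mpo 5.22-fold (adjusted p = 0.0142). S100a9 rose by 2.07 log2 (adjusted p = 0.0258). The calls of S100a8, S100a9, Ltf and Lcn2 were lost without any WT array or Zeb2 Id2 DKO replicate 2 (adjusted p up to 0.283, 0.261, 0.236 and 0.329). Ltf and Lcn2 were also lost without either Nfil3 Zeb2 DKO array, and Mpo without either Zeb2 Id2 DKO array (up to 0.185). The neutrophil list was higher by camera (median log2 fold change 1.24, adjusted p = 2.89e-14, and adjusted p = 0.149 with an estimated correlation). Erythroid genes were higher as well: 2 of 11 rose (9 when adjusted over the list alone), Car2, a carbonic anhydrase gene (log2 1.06, adjusted p = 0.0118), and Hemgn (0.90, adjusted p = 0.0142). Both were lost without either Zeb2 Id2 DKO array, and Hemgn also without WT replicate 2 (adjusted p up to 0.128 and 0.145). That list was higher by camera (median 0.83, adjusted p = 1.18e-11, and adjusted p = 0.149 with an estimated correlation).

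Most T cell genes lay lower in the Zeb2 Id2 DKO arrays than in WT. Of 17 T cell genes 3 fell and 1 rose (11 and 1 when adjusted over the list alone): the CD3 chains Cd3d (log2 -0.87, adjusted p = 0.00695; 0.0974 without Zeb2 Id2 DKO replicate 1) and Cd3g (-0.99, adjusted p = 0.0127; up to 0.157 without WT replicate 2 or 3 or Zeb2 Id2 DKO replicate 1), and Lat (-0.62, adjusted p = 0.045). The call of Lat was lost with any array but WT replicate 1 and Zeb2 KO replicate 3 left out (adjusted p up to 0.405). Cd6 rose 3.54-fold (8.73 ± 0.14 against 6.91 ± 0.20, adjusted p = 0.000372). The T cell list was lower by camera (median -0.32, adjusted p = 4.34e-06, and adjusted p = 0.149 with an estimated correlation). Of 17 NK cell genes Il2rb fell (log2 -0.96, adjusted p = 0.0328), and 2 fell when adjusted over the list alone. The Il2rb call was lost without WT replicate 1 or 3 or any Nfil3 Zeb2 DKO or Zeb2 Id2 DKO array (adjusted p up to 0.332). The NK cell list was lower by camera (median -0.36, adjusted p = 0.0128, and adjusted p = 0.288 with an estimated correlation). The list had an adjusted p of 0.0855 without WT replicate 3 and 0.105 without Zeb2 Id2 DKO replicate 1. B cell genes, with 0 of 20 called (1 fell when adjusted over the list alone), did not pass (median -0.23, adjusted p = 0.108). The adjusted p of this list was 0.00227 and 0.00547 without WT replicate 2 or 3.

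Among macrophage and monocyte genes, the red pulp macrophage genes Hpgd (log2 -1.61, adjusted p = 0.0115) and Vcam1 (-1.06, adjusted p = 0.0328) fell in Zeb2 Id2 DKO, 2 of 21 (4 when adjusted over the list alone). Both calls were lost without WT replicate 3 or either Zeb2 Id2 DKO array, and Vcam1 also without WT replicate 2 or either Nfil3 Zeb2 DKO array (adjusted p up to 0.128 and 0.345). That list was lower by camera (median -0.12, adjusted p = 0.00555, and adjusted p = 0.297 with an estimated correlation). The list's adjusted p was 0.0925 without Zeb2 Id2 DKO replicate 1. The monocyte gene Ms4a6c rose (log2 0.68, adjusted p = 0.045), 1 of 20, and 5 rose and 1 fell when adjusted over the list alone. It was lost with any array but Zeb2 KO replicates 1 and 3 left out (adjusted p up to 0.302). The monocyte list was higher by camera (median 0.17, adjusted p = 0.00683, and adjusted p = 0.214 with an estimated correlation). That list's adjusted p was 0.174 without Zeb2 Id2 DKO replicate 2. Immediate early and stress genes, 0 of 22 called (1 fell when adjusted over the list alone), were lower by camera (median -0.19, adjusted p = 0.00377, and adjusted p = 0.392 with an estimated correlation). For this list the adjusted p became 0.207 without Zeb2 Id2 DKO replicate 1. Of 17 Toll-like receptor genes Tlr9, the receptor for unmethylated DNA, rose (log2 0.61, adjusted p = 0.0461), and 5 rose and 1 fell when adjusted over the list alone. Tlr9 was lost with any array but WT replicate 2 and Zeb2 KO replicate 3 left out (adjusted p up to 0.365). The Toll-like receptor list did not pass (median 0.04, adjusted p = 0.0618). This list's adjusted p was 0.0282 without WT replicate 2, 0.0213 without Zeb2 Id2 DKO replicate 1. MHC class I (median 0.02, adjusted p = 0.749), MHC class II (-0.01, adjusted p = 0.133) and cell cycle genes (-0.08, adjusted p = 0.459; 0.000342 without WT replicate 1) did not pass and held no called member, though 1 MHC class II gene fell when adjusted over the list alone.

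**Figure D3:**
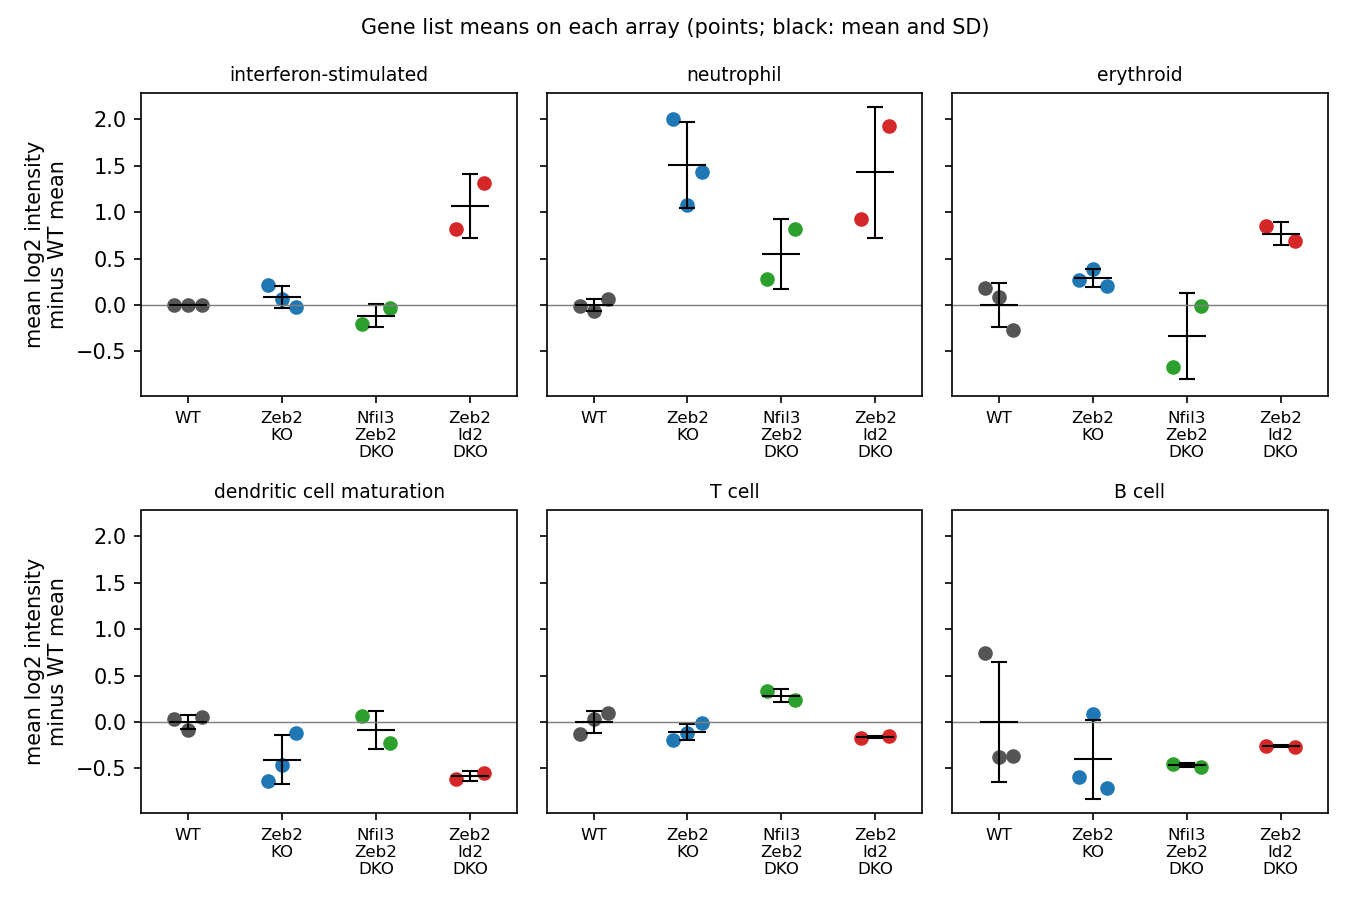
Mean log2 intensity minus the WT mean of 6 gene lists in each array (points) by genotype, with group means and standard deviations. The interferon-stimulated list stood at 0.82 and 1.31 in the Zeb2 Id2 DKO arrays, and the neutrophil list at 1.08 to 2.0 in Zeb2 KO.

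Between the Zeb2 KO and WT arrays, 4 genes were differentially expressed: 1 up-regulated and 3 down-regulated. Ngp rose 8.06-fold (11.56 ± 0.54 against 8.55 ± 0.17, log2 3.01 [2.25 to 3.77], adjusted p = 0.0255). Rtn1, a reticulon of the endoplasmic reticulum, fell 2.16-fold (8.52 ± 0.25 against 9.64 ± 0.15, log2 -1.11 [-1.39 to -0.84], adjusted p = 0.0255), Zfyve9, an adaptor of TGF-beta signalling, 1.86-fold (6.03 ± 0.06 against 6.92 ± 0.16, log2 -0.89 [-1.10 to -0.68], adjusted p = 0.0255) and Cd80 1.64-fold (9.75 ± 0.11 against 10.46 ± 0.12, log2 -0.71 [-0.91 to -0.51], adjusted p = 0.0442). The arrays of both groups did not overlap in these genes, which calling by p favours. Values that did not pass included S100a9 (log2 fold change 2.24, adjusted p = 0.106), Carhsp1 (0.54, adjusted p = 0.117), Adgrl3 (-1.28, adjusted p = 0.0508), Il12b (10.01 ± 0.19 against 11.10 ± 0.13, -1.09, adjusted p = 0.0508) and the nuclear receptor gene Nr4a3 (-0.74, adjusted p = 0.0508).

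All 4 calls between Zeb2 KO and WT were lost without WT replicate 2 or 3 or Zeb2 KO replicate 1 or 2 (adjusted p up to 0.181 for Ngp, Rtn1 and Zfyve9 and 0.228 for Cd80). Ngp and Rtn1 were also lost without either Nfil3 Zeb2 DKO array, and Cd80 without any Nfil3 Zeb2 DKO or Zeb2 Id2 DKO array. An unadjusted p under 0.05 was found for 1474 genes against 997 expected by chance. The count of 4 became 0 without WT replicate 2, 1 without WT replicate 3, 0 without Zeb2 KO replicate 1 or 2, 22 without WT replicate 1 and 165 without Zeb2 KO replicate 3. It was 2 without either Nfil3 Zeb2 DKO array, 7 without either Zeb2 Id2 DKO array, and 500 without both WT replicate 1 and Zeb2 KO replicate 3. Zeb2 KO replicate 3 stood apart from the other arrays, at 25.8 and -24.6 on principal components 1 and 2 (32.6% and 21.2% of the variance) and with an array weight of 0.187.

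Neutrophil genes stood higher in the Zeb2 KO arrays than in WT. Ngp rose, 1 of 17 members, and 14 rose when adjusted over the list alone; 16 of 17 had positive values. Lcn2 (10.04 ± 0.68 against 6.97 ± 0.37, log2 3.07, adjusted p = 0.107), the calcium-binding S100a9 (2.24, adjusted p = 0.106) and Ltf (2.80, adjusted p = 0.117) had large values that did not pass over all genes. The list was higher by camera (median log2 fold change 1.26, adjusted p = 1.24e-23, and adjusted p = 0.164 with an estimated correlation), with array means 2.0, 1.08 and 1.43 above WT. Erythroid genes, 0 of 11 called (1 rose when adjusted over the list alone), were higher by camera (median 0.29, adjusted p = 0.000412, and adjusted p = 0.271 with an estimated correlation), with Car2 at a log2 fold change of 0.57.

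Maturation genes lay lower in Zeb2 KO than in WT, in arrays in which neutrophil genes lay higher. Of 26 members Cd80 fell (5 when adjusted over the list alone) and no member had a positive value. Il12b, Serpinb9, an inhibitor of granzyme B (log2 fold change -0.64, adjusted p = 0.212), and Cd200 (-0.53, adjusted p = 0.357) did not pass over all genes. The list was lower by camera (median -0.40, adjusted p = 1.42e-14, and adjusted p = 0.228 with an estimated correlation), with array means -0.63, -0.47 and -0.12 from WT, the last in Zeb2 KO replicate 3. Of 25 cDC2 genes Rtn1 fell (7 fell and 1 rose when adjusted over the list alone). The beta-glucan receptor gene Clec7a (log2 fold change -1.08, adjusted p = 0.106) and Cd209a (-1.40, adjusted p = 0.168) did not pass over all genes, and the list was lower by camera (median -0.26, adjusted p = 4.63e-10, and adjusted p = 0.164 with an estimated correlation). Immediate early and stress genes, with 0 of 22 called by either adjustment and no positive value, were lower by camera (median -0.23, adjusted p = 2.95e-08, and adjusted p = 0.271 with an estimated correlation). Examples were Btg2 (-0.61) and Junb (-0.47).

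B cell genes in Zeb2 KO, 0 of 20 called (1 fell when adjusted over the list alone), were lower by camera (median -0.30, adjusted p = 6.61e-05, and adjusted p = 0.332 with an estimated correlation). This hung on WT replicate 1, whose B cell mean lay 0.74 above the WT mean against -0.37 in both other WT arrays; without it the direction turned (adjusted p = 0.762). Ms4a1, which encodes CD20, stood at 8.57 ± 1.06 in WT (log2 fold change -2.03, adjusted p = 0.213). T cell genes, 0 of 17 called (1 rose and 5 fell when adjusted over the list alone), were lower by camera (median -0.12, adjusted p = 0.0011, and adjusted p = 0.271 with an estimated correlation), with Cd3d at -0.52 and Cd6 at 0.70 (adjusted p = 0.212 for both). Red pulp macrophage genes, 0 of 21 called (2 fell when adjusted over the list alone), were lower (median -0.10, adjusted p = 0.0015, and adjusted p = 0.331 with an estimated correlation). The list had an adjusted p of 0.112 without Zeb2 KO replicate 1. Hpgd had -1.21 (adjusted p = 0.168).

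In 3 further lists no member was called over all genes and left-out arrays ended the camera call between Zeb2 KO and WT. The pDC list was lower (30 members, 3 fell when adjusted over the list alone, median -0.12, adjusted p = 0.0273, and adjusted p = 0.239 with an estimated correlation), with Cd300c at -0.75. For this list the adjusted p became 0.0917, 0.0735 and 0.0530 without WT replicate 1, Zeb2 KO replicate 1 or 2. Interferon-stimulated genes were higher (25 members, median 0.09, adjusted p = 0.0382, and adjusted p = 0.515 with an estimated correlation). The adjusted p of this list was 0.0649, 0.0689, 0.540 and 0.130 without WT replicate 2, WT replicate 3, Zeb2 KO replicate 1 or 2. Toll-like receptor genes were lower (17 members, 1 fell when adjusted over the list alone, median -0.10, adjusted p = 0.0382, and adjusted p = 0.271 with an estimated correlation; 0.155, 0.0838 and 0.447 without WT replicate 2, Zeb2 KO replicate 2 or 3), with Tlr1 at -0.82 (adjusted p = 0.184).

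Genes of cDC1 identity did not pass as a list between Zeb2 KO and WT (median -0.04, adjusted p = 0.253, and 0.0369, lower, without Zeb2 KO replicate 1). Cd8a stood at -0.41 (adjusted p = 0.370), Cd207 at -0.70 (adjusted p = 0.448) and Ly75 at -0.39 (adjusted p = 0.419). No pass was found for E and ID proteins (median -0.09, adjusted p = 0.192), dendritic cell transcription factors other than Nfil3 and Zeb2 (median 0.01, mean -0.04, camera direction down, adjusted p = 0.612) or monocyte genes (-0.10, adjusted p = 0.167; 0.0267, lower, without Zeb2 KO replicate 1; 3 rose and 2 fell when adjusted over the list alone). NK cell genes (median -0.12, adjusted p = 0.167; 0.00532, lower, without WT replicate 2), MHC class I (0.04, adjusted p = 0.438) and MHC class II genes (-0.06, adjusted p = 0.112; 0.0398, lower, without Zeb2 KO replicate 3) did not pass. Cell cycle genes (median 0.02, adjusted p = 0.306) came under 0.05 in opposite directions: lower without WT replicate 1 (0.0232) or Zeb2 KO replicate 3 (0.0297), higher without WT replicate 3 (0.00303), Zeb2 KO replicate 1 (0.0376) or 2 (0.0448).

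**Figure D4:**
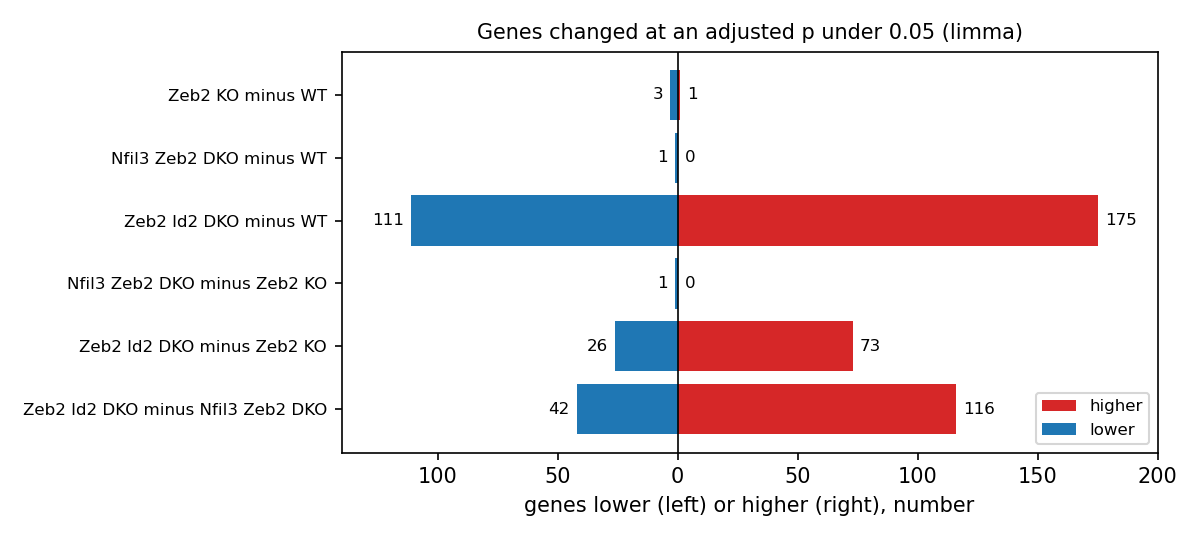
Number of genes lower (left) and higher (right) at an adjusted p under 0.05 in each of the 6 comparisons. The 3 comparisons with Zeb2 Id2 DKO had 286, 99 and 158 genes, and the other 3 had 4, 1 and 1.

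Between the Nfil3 Zeb2 DKO and WT arrays the only changed gene was the target Nfil3 (1 down-regulated, none up-regulated). Values that did not pass included Auh, which encodes an enzyme of leucine breakdown (8.98 ± 0.04 against 7.74 ± 0.11, log2 fold change 1.24), Cd6 (0.88), Adgrl3 (-1.09), Clec7a (-0.99), Ramp3 (-0.72), Dusp4 (-0.66) and Trim35 (-0.40), all at an adjusted p of 0.512. Cd8a had a log2 fold change of 0.10. An unadjusted p under 0.05 was found for 829 genes against 997 expected by chance. The count of 1 became 2 without WT replicate 1 or 3 and 7 without Zeb2 KO replicate 3. It was 62 without both WT replicate 1 and Zeb2 KO replicate 3.

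Immediate early and stress genes were lower by camera in Nfil3 Zeb2 DKO than in WT, with 0 of 22 called and 1 falling when adjusted over the list alone (median -0.27, adjusted p = 1.36e-08, and adjusted p = 0.482 with an estimated correlation). Egr2 (log2 fold change -0.78) and Nr4a3 (-0.54) did not pass over all genes (adjusted p = 0.522 for both). T cell genes, 0 of 17 called (2 rose when adjusted over the list alone) and 16 with positive values, were higher (median 0.13, mean 0.28, adjusted p = 2.07e-06, and adjusted p = 0.328 with an estimated correlation). Cd8b1, the CD8 beta chain gene, had a log2 fold change of 1.75 (9.24 ± 0.09 against 7.49 ± 0.49, adjusted p = 0.522). The T cell list stood 0.33 and 0.24 above the WT mean in the 2 Nfil3 Zeb2 DKO arrays, in which the neutrophil list stood 0.28 and 0.81 above it.

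For 7 lists the camera call between Nfil3 Zeb2 DKO and WT was ended by a left-out array. B cell genes were lower (median -0.50, adjusted p = 2.07e-06, and adjusted p = 0.498 with an estimated correlation), with Bank1 at -0.99. The list had an adjusted p of 0.286 without WT replicate 1. Neutrophil genes were higher (1 rose and 1 fell when adjusted over the list alone, median 0.35, adjusted p = 0.000293, and adjusted p = 0.619 with an estimated correlation), with Ngp at 1.52 (adjusted p = 0.766) and Il1b at -0.45 (adjusted p = 0.677). The adjusted p of this list was 0.326 without Nfil3 Zeb2 DKO replicate 2. NK cell genes were higher (median 0.18, adjusted p = 0.00299, and adjusted p = 0.498 with an estimated correlation). The list's adjusted p was 0.114 without WT replicate 2 and 0.110 without Nfil3 Zeb2 DKO replicate 2. Erythroid genes were lower (median -0.23, adjusted p = 0.00299, and adjusted p = 0.561 with an estimated correlation), with Car1 at -1.31 (adjusted p = 0.984). The list's adjusted p was 0.123 without WT replicate 1 and 0.919 without Nfil3 Zeb2 DKO replicate 1. Dendritic cell transcription factors other than the targeted Nfil3 and Zeb2, 0 of 31 called, were lower (median -0.04, adjusted p = 0.0305, and adjusted p = 0.327 with an estimated correlation). That list did not pass without WT replicate 1 or Nfil3 Zeb2 DKO replicate 2 (adjusted p up to 0.350). Maturation genes were lower (median -0.08, adjusted p = 0.0156, and adjusted p = 0.750 with an estimated correlation; 0.123 and 0.0593 without WT replicate 1 or 3), and turned direction without Nfil3 Zeb2 DKO replicate 2 (0.642). Interferon-stimulated genes were lower (median -0.06, adjusted p = 0.0349, and adjusted p = 0.755 with an estimated correlation). For this list the adjusted p became 0.123, 0.0533 and 0.578 without WT replicate 1, Zeb2 KO replicate 3 or Nfil3 Zeb2 DKO replicate 1.

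The cDC1 identity list did not pass between Nfil3 Zeb2 DKO and WT (median -0.01, adjusted p = 0.174). The cDC2 list (median 0.00, mean -0.07, adjusted p = 0.112; 2 fell when adjusted over the list alone) came under 0.05, lower, without WT replicate 1 (0.00143) or Nfil3 Zeb2 DKO replicate 1 (0.000645). Red pulp macrophage genes (median -0.04, adjusted p = 0.164; 1 fell when adjusted over the list alone) did so without WT replicate 1 (0.0128). Cell cycle genes (0.05, adjusted p = 0.610) did so in opposite directions: lower without WT replicate 1 (0.0128), higher without WT replicate 3 (0.00399) or Nfil3 Zeb2 DKO replicate 1 (0.0265). No pass was found for pDC (median 0.01, mean -0.03, camera direction up, adjusted p = 0.625), E and ID protein (0.01, adjusted p = 0.965), monocyte (median 0.05, mean -0.03, camera direction down, adjusted p = 0.813), MHC class I (0.00, adjusted p = 0.610), MHC class II (-0.02, adjusted p = 0.610) and Toll-like receptor genes (0.03, adjusted p = 0.865).

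Nfil3 was also the only changed gene between Nfil3 Zeb2 DKO and Zeb2 KO, 11.9-fold lower (log2 -3.58 [-4.17 to -2.99], adjusted p = 0.00125). Auh stood 1.56 log2 higher [1.08 to 2.04] in Nfil3 Zeb2 DKO (8.98 ± 0.04 against 7.42 ± 0.50) and did not pass (adjusted p = 0.152); it passed without Zeb2 KO replicate 3 (log2 fold change 1.27). Other values that did not pass were Il12b (1.0, adjusted p = 0.295), Btbd19 (0.82, adjusted p = 0.295), Lsmem1 (0.65), Cd1d1, an antigen-presenting molecule for lipids (0.61, adjusted p = 0.374), Carhsp1 (-0.77, adjusted p = 0.0991), Slc7a8 (-0.77, adjusted p = 0.295), Adgrl2 (-0.69, adjusted p = 0.314) and Hadha (-0.56, adjusted p = 0.374). Cd8a (0.52, adjusted p = 0.374), Itgae (-0.76, adjusted p = 0.379) and Siglech (0.62, adjusted p = 0.394) did not pass. An unadjusted p under 0.05 was found for 1695 genes against 997 by chance. The count of 1 became 4 without WT replicate 1 and 106 without Zeb2 KO replicate 3. It was 266 without both WT replicate 1 and Zeb2 KO replicate 3.

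Neutrophil genes stood lower and T cell genes higher in Nfil3 Zeb2 DKO than in Zeb2 KO. Of 17 neutrophil genes none was called (11 fell when adjusted over the list alone), none had a positive value, and the list was lower by camera (median -1.04, adjusted p = 3.05e-13, and adjusted p = 0.203 with an estimated correlation). Ngp had a log2 fold change of -1.49 (adjusted p = 0.374), Ltf -1.76 (adjusted p = 0.394) and the histamine-forming enzyme gene Hdc -1.02. All 17 T cell genes had positive values (0 called, 10 rose when adjusted over the list alone), and the list was higher (median 0.29, adjusted p = 2.40e-11, and adjusted p = 0.195 with an estimated correlation), with Cd3g at 0.79 (adjusted p = 0.374) and Cd3d at 0.56. Erythroid genes were lower (0 of 11 called, 7 fell when adjusted over the list alone, median -0.63, adjusted p = 1.56e-07, and adjusted p = 0.203 with an estimated correlation), with Car2 at -0.80 (adjusted p = 0.374). NK cell genes were higher (0 of 17 called, 3 rose when adjusted over the list alone, median 0.15, adjusted p = 0.000498, and adjusted p = 0.250 with an estimated correlation).

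In the same arrays maturation genes were higher (0 of 26 called, 1 rose when adjusted over the list alone, 25 with positive values, median 0.31, adjusted p = 7.88e-07, and adjusted p = 0.304 with an estimated correlation). So were cDC2 genes (0 of 25 called, 5 rose when adjusted over the list alone, median 0.26, adjusted p = 6.03e-05, and adjusted p = 0.203 with an estimated correlation), with Cd209a at 1.34 (adjusted p = 0.374) and S100a4 at 0.93. Genes of the pDC list were higher (0 of 30 called, 5 rose when adjusted over the list alone, median 0.08, adjusted p = 0.0184, and adjusted p = 0.203 with an estimated correlation). This list's adjusted p was 0.121 without Nfil3 Zeb2 DKO replicate 1. Interferon-stimulated genes were lower (0 of 25 called, 2 with positive values, median -0.12, adjusted p = 0.000179, and adjusted p = 0.408 with an estimated correlation).

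Between Nfil3 Zeb2 DKO and Zeb2 KO, dendritic cell transcription factors other than Nfil3 and Zeb2 (median -0.03, 0 of 31 called) did not pass as a list (adjusted p = 0.253). Red pulp macrophage (median 0.09, adjusted p = 0.151; 0.00202, higher) and MHC class I genes (-0.05, adjusted p = 0.312; 0.0479, lower) came under 0.05 without Zeb2 KO replicate 3. Without the same array cell cycle genes turned direction (median 0.08, camera direction down, adjusted p = 0.866; 0.0143, higher). Toll-like receptor genes (0.06, adjusted p = 0.105; 3 rose when adjusted over the list alone) came under 0.05, higher, without Zeb2 KO replicate 1 (0.0110). No pass was found for cDC1 identity (median 0.03, camera direction down, adjusted p = 0.886; 1 rose and 1 fell when adjusted over the list alone), E and ID protein (0.10, adjusted p = 0.334), monocyte (0.00, adjusted p = 0.618; 2 rose and 1 fell when adjusted over the list alone), B cell (-0.13, adjusted p = 0.684), MHC class II (0.05, adjusted p = 0.450) and immediate early genes (0.05, camera direction down, adjusted p = 0.886).

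Between Zeb2 Id2 DKO and Zeb2 KO, 99 genes were differentially expressed: 73 up-regulated and 26 down-regulated, 35 and 8 of them by at least 2-fold. Carmil1 rose 10.8-fold (10.30 ± 0.13 against 6.87 ± 0.29, log2 3.43 [3.08 to 3.77], adjusted p = 4.09e-06), Lrrc4c 5.48-fold (adjusted p = 1.42e-05), Adgrl2 4.22-fold (8.88 ± 0.05 against 6.80 ± 0.01, adjusted p = 1.50e-05) and the Schlafen family gene Slfn1 3.68-fold (8.63 ± 0.29 against 6.75 ± 0.12, adjusted p = 0.00012). Id2 was 34.1-fold lower (adjusted p = 1.01e-08). Frmd4b fell 2.03-fold (8.63 ± 0.09 against 9.65 ± 0.11, adjusted p = 0.00137) and Smad3, a transducer of TGF-beta signals, 2.0-fold (7.01 ± 0.16 against 8.01 ± 0.13, log2 -1.0 [-1.24 to -0.76], adjusted p = 0.00261). No left-out array ended these calls.

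Further rises against Zeb2 KO were Plet1 (4.87-fold, adjusted p = 0.0245; lost without WT replicate 3, Zeb2 KO replicate 1 or 2, either Nfil3 Zeb2 DKO array or Zeb2 Id2 DKO replicate 1, up to 0.254) and the kinase gene Dapk2 (4.38-fold, adjusted p = 0.00725; up to 0.107). Falls were Apol7c (4.01-fold, adjusted p = 0.0161; lost without Zeb2 KO replicate 2 or Zeb2 Id2 DKO replicate 1, up to 0.194), Cpne8 (2.64-fold, adjusted p = 0.00779; up to 0.108), Icos (2.30-fold, adjusted p = 0.0186; up to 0.266), Adgrl3 (2.30-fold, adjusted p = 0.0193; up to 0.203) and Adam22 (1.94-fold, adjusted p = 0.0124; up to 0.186). Dapk2, Cpne8, Icos, Adgrl3 and Adam22 were lost without either Zeb2 Id2 DKO array, Icos also without Zeb2 KO replicate 2 and Adgrl3 without Zeb2 KO replicate 1 or 2. Ocstamp, known from osteoclast fusion, fell 2.25-fold (adjusted p = 0.00779; 0.117 without Zeb2 Id2 DKO replicate 1) and the chemokine gene Ccl2 1.94-fold (adjusted p = 0.0251). The Ccl2 call was lost without WT replicate 3, Zeb2 KO replicate 1 or 2, either Nfil3 Zeb2 DKO array or Zeb2 Id2 DKO replicate 1 (adjusted p up to 0.288). An unadjusted p under 0.05 was found for 1465 genes against 997 by chance, and the arrays of both groups did not overlap in any of the 99 called genes. The count moved to 53 without Zeb2 KO replicate 2 and 245 without both WT replicate 1 and Zeb2 KO replicate 3.

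Interferon-stimulated genes rose against Zeb2 KO as well: 13 of 25 rose, none fell (21 rose when adjusted over the list alone), and all 25 had positive values. Ifit2 (4.47-fold, adjusted p = 0.00128), Ifit3 (4.40-fold, adjusted p = 0.000376), Ifit1 (3.71-fold, adjusted p = 0.00128) and Oasl2 (3.42-fold, adjusted p = 0.000902) kept their calls with each array left out. The list was higher by camera (median 0.93, adjusted p = 3.11e-41, and adjusted p = 0.0322 with an estimated correlation). Siglech rose 3.75-fold (7.99 ± 0.12 against 6.08 ± 0.21, log2 1.91 [1.51 to 2.31], adjusted p = 0.00128), Cd300c 3.14-fold (9.79 ± 0.26 against 8.13 ± 0.24, adjusted p = 0.00292; 0.0550 without Zeb2 Id2 DKO replicate 1) and Bst2, also an interferon-induced gene, 2.06-fold (adjusted p = 0.0488; up to 0.414, lost with any array but Zeb2 KO replicates 1 and 3 left out). These were the 3 of 30 pDC genes that rose (6 when adjusted over the list alone), and the pDC list was higher by camera (median 0.17, adjusted p = 1.23e-05, and adjusted p = 0.0322 with an estimated correlation). The neutrophil list did not pass in this comparison (median -0.12, adjusted p = 0.424): it came under 0.05 lower without Zeb2 KO replicate 2 (0.00464) or Zeb2 Id2 DKO replicate 2 (3.67e-07) and higher without Zeb2 Id2 DKO replicate 1 (0.000395). Erythroid genes, 0 of 11 called (1 rose when adjusted over the list alone), were higher (median 0.50, adjusted p = 6.65e-07, and adjusted p = 0.149 with an estimated correlation), with Hemgn at 0.55 and Car2 at 0.49.

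Toll-like receptor genes were higher by camera in Zeb2 Id2 DKO than in Zeb2 KO (0 of 17 called, 1 rose when adjusted over the list alone, median 0.19, adjusted p = 2.36e-05, and adjusted p = 0.0596 with an estimated correlation), with Tlr9 at 0.50 and Tlr13 at 0.29. So were monocyte genes (0 of 20 called, 4 rose when adjusted over the list alone, median 0.27, adjusted p = 5.90e-05, and adjusted p = 0.112 with an estimated correlation), with Ms4a6c at 0.75 (adjusted p = 0.0545) and the fractalkine receptor gene Cx3cr1 at 0.90 (adjusted p = 0.146). Dendritic cell transcription factors other than Nfil3 and Zeb2 were higher (0 of 31 called, median 0.06, adjusted p = 0.0186, and adjusted p = 0.0953 with an estimated correlation), with Notch2 at 0.46 and Runx1 at 0.39. That list's adjusted p was 0.171 without Zeb2 Id2 DKO replicate 2. Genes of the cDC2 list were higher (0 of 25 called, 1 rose when adjusted over the list alone, median 0.13, adjusted p = 0.0319, and adjusted p = 0.462 with an estimated correlation). The adjusted p of this list was 0.0568, 0.101 and 0.376 without Zeb2 KO replicate 1, Zeb2 KO replicate 2 or Zeb2 Id2 DKO replicate 2. T cell genes were lower (median -0.17, adjusted p = 0.0197, and adjusted p = 0.462 with an estimated correlation; 0.0670 and 0.139 without Zeb2 KO replicate 2 or 3), though the only called member, Cd6, rose (2.19-fold, adjusted p = 0.0116). That call was lost without either Zeb2 Id2 DKO array (adjusted p up to 0.176).

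Within cDC1 identity, 2 of 32 genes fell against Zeb2 KO, Id2 and Cadm1 (1.58-fold, adjusted p = 0.0187; lost without either Zeb2 Id2 DKO array, up to 0.261), and 1 rose and 2 fell when adjusted over the list alone. Without Id2 the list did not pass (median 0.06, mean 0.03, adjusted p = 0.218; 0.0497 without Zeb2 KO replicate 1). Maturation genes (Apol7c fell, 1 of 26; median -0.07, adjusted p = 0.235; 0.0189, lower, without Zeb2 KO replicate 1) and E and ID proteins other than Id2 (0 of 6 called; -0.02, adjusted p = 0.824) did not pass. NK cell genes (-0.17, adjusted p = 0.0654, 1 rose and 1 fell when adjusted over the list alone) came under 0.05, lower, without WT replicate 2 (0.0416) or 3 (0.0191), either Nfil3 Zeb2 DKO array (0.0457) or Zeb2 Id2 DKO replicate 2 (0.0304). B cell genes (0.11, adjusted p = 0.0978; 0.000292, higher, without Zeb2 KO replicate 2), cell cycle genes (-0.09, adjusted p = 0.0978; 0.0203 and 0.00982, lower, without Zeb2 KO replicate 1 or 2) and immediate early genes (0.04, adjusted p = 0.214; 0.0117 and 0.00463, higher, without Zeb2 KO replicate 3 or Zeb2 Id2 DKO replicate 1) did not pass. Neither did red pulp macrophage (0.00, adjusted p = 0.583), MHC class I (0.00, adjusted p = 0.825) and MHC class II genes (-0.02, adjusted p = 0.825).

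Between the 2 double knockouts, 158 genes differed: 116 were higher and 42 lower in Zeb2 Id2 DKO than in Nfil3 Zeb2 DKO, 56 and 17 of them by at least 2-fold. Both targets differed as labelled, Nfil3 12.2-fold higher (adjusted p = 0.000403) and Id2 43.9-fold lower (adjusted p = 1.28e-08). Carmil1 rose 7.14-fold (10.30 ± 0.13 against 7.46 ± 0.17, adjusted p = 4.79e-05), Adgrl2 6.79-fold (8.88 ± 0.05 against 6.11 ± 0.03, adjusted p = 4.11e-06), Lrrc4c 4.74-fold (adjusted p = 6.61e-05) and Ank1, an ankyrin of the red cell membrane skeleton, 4.43-fold (9.02 ± 0.28 against 6.88 ± 0.23, adjusted p = 0.000375). Cpne8 fell 3.40-fold (adjusted p = 0.00284) and Adam22 2.59-fold (adjusted p = 0.00284). No left-out array ended these calls.

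Calls between the double knockouts that a left-out array ended included Plet1 (5.86-fold higher, adjusted p = 0.0162; up to 0.154), Rhag (5.64-fold higher, 7.50 ± 0.33 against 5.00 ± 1.22, adjusted p = 0.0335; up to 0.229) and the growth factor receptor gene Fgfr1 (4.60-fold higher, adjusted p = 0.0111; up to 0.154). Plet1 and Fgfr1 were lost without either Nfil3 Zeb2 DKO array or Zeb2 Id2 DKO replicate 1. Rhag was lost without WT replicate 2 or 3, Zeb2 KO replicate 1, Nfil3 Zeb2 DKO replicate 1 or either Zeb2 Id2 DKO array. Among the falls were Apol7c (6.87-fold, 8.36 ± 0.87 against 11.15 ± 0.06, adjusted p = 0.00362; 0.0702 without Nfil3 Zeb2 DKO replicate 1), H2-M2 (3.25-fold, adjusted p = 0.0215; up to 0.259), Adgrl3 (2.62-fold, adjusted p = 0.0114; up to 0.112), Ctla2a (2.48-fold, adjusted p = 0.0281; up to 0.258) and Auh (2.38-fold, adjusted p = 0.0431; up to 0.292). H2-M2, Adgrl3 and Ctla2a were lost without any double knockout array, and Auh without these or any WT array. An unadjusted p under 0.05 was found for 2292 genes against 997 by chance, and the arrays of both groups did not overlap in any called gene. The count was lower with any double knockout array left out. It moved to 704 without Zeb2 KO replicate 3 and 958 without both WT replicate 1 and Zeb2 KO replicate 3.

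Interferon-stimulated genes were higher in Zeb2 Id2 DKO than in Nfil3 Zeb2 DKO: 13 of 25 rose and none fell (22 rose when adjusted over the list alone). Ifit2 rose 5.28-fold (9.38 ± 0.54 against 6.98 ± 0.25, adjusted p = 0.000942) and Ifit3 4.78-fold (adjusted p = 0.000403), and the list was higher by camera (median 1.0, adjusted p = 1.81e-38, and adjusted p = 0.0368 with an estimated correlation). Siglech rose 2.44-fold (7.99 ± 0.12 against 6.70 ± 0.24, adjusted p = 0.0149, lost without any double knockout array, up to 0.142). With it rose Cd300c (2.03-fold, adjusted p = 0.0472; lost without WT replicate 2 or 3 or any double knockout array, up to 0.374) and Upb1 (1.49-fold, adjusted p = 0.0370). The Upb1 call was lost with any array but Zeb2 KO replicates 1 and 3 left out (adjusted p up to 0.297). These were 3 of 30 pDC genes (5 rose and 2 fell when adjusted over the list alone), and the list did not pass (median 0.12, adjusted p = 0.0614). The list's adjusted p was 0.0447, 0.0170 and 0.0238 without WT replicate 1, Nfil3 Zeb2 DKO replicate 1 or Zeb2 Id2 DKO replicate 2. Dendritic cell transcription factors other than the targeted Nfil3 and Zeb2, 0 of 31 called, were higher by camera (median 0.14, adjusted p = 0.00191, and adjusted p = 0.0573 with an estimated correlation).

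Erythroid genes were higher and T cell genes lower in the same comparison. Of 11 erythroid genes 3 rose (9 when adjusted over the list alone): Epb42, a red cell membrane protein gene (2.65-fold, adjusted p = 0.0289), Car2 (2.45-fold, adjusted p = 0.00957) and Hemgn (2.0-fold, adjusted p = 0.0176), all lost without Nfil3 Zeb2 DKO replicate 1 or either Zeb2 Id2 DKO array (up to 0.297, 0.120 and 0.216). The list was higher by camera (median 1.13, adjusted p = 1.38e-13, and adjusted p = 0.0576 with an estimated correlation), and the neutrophil list too (0 of 17 called, 3 rose when adjusted over the list alone, median 0.90, adjusted p = 6.67e-08, and adjusted p = 0.287 with an estimated correlation). Of 17 T cell genes Cd3g (2.50-fold, adjusted p = 0.00618; lost without Nfil3 Zeb2 DKO replicate 1 or Zeb2 Id2 DKO replicate 1, up to 0.102), Cd3d (1.88-fold, adjusted p = 0.012; up to 0.129) and Txk (1.71-fold, adjusted p = 0.0335; up to 0.286) fell. Cd6 rose (1.93-fold, adjusted p = 0.0379, and up to 0.293). Cd3d was lost without either Nfil3 Zeb2 DKO array or Zeb2 Id2 DKO replicate 1, Txk without any double knockout array or WT replicate 2, and Cd6 without these or WT replicate 3. When adjusted over the list alone 11 fell and 1 rose, and the list was lower by camera (median -0.45, adjusted p = 1.02e-10, and adjusted p = 0.0576 with an estimated correlation). NK cell genes were lower (2 of 17 fell, Txk and Il2rb; 3 when adjusted over the list alone; median -0.28, adjusted p = 0.000101, and adjusted p = 0.253 with an estimated correlation), with Il2rb, a chain of the interleukin 2 receptor, 2.98-fold lower (adjusted p = 0.00618). The Il2rb call was lost without Nfil3 Zeb2 DKO replicate 1 or Zeb2 Id2 DKO replicate 2 (adjusted p up to 0.102).

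Maturation genes were lower in Zeb2 Id2 DKO than in Nfil3 Zeb2 DKO, with 2 of 26 falling, Apol7c and Il12b (log2 -0.97; lost with any WT or Zeb2 Id2 DKO array, Zeb2 KO replicate 2 or Nfil3 Zeb2 DKO replicate 1 left out, adjusted p up to 0.293), and 8 when adjusted over the list alone (median -0.31, adjusted p = 2.63e-06, and adjusted p = 0.287 with an estimated correlation). Monocyte genes were higher (0 of 20 called, median 0.16, adjusted p = 0.00609, and adjusted p = 0.257 with an estimated correlation), with Ccr2 at 0.89 and Lyz2 at 0.73. For this list the adjusted p became 0.154 without Zeb2 Id2 DKO replicate 2. Within cDC1 identity Fkbp1b rose (1.83-fold, adjusted p = 0.0311; lost without WT replicate 2 or 3 or any double knockout array, up to 0.327), and Id2 and Cadm1 fell (Cadm1 1.65-fold, adjusted p = 0.0146). The Cadm1 call was lost without any double knockout array (adjusted p up to 0.174). When adjusted over the list alone 4 rose and 3 fell, and without Id2 the list did not pass (median 0.04, mean 0.03, adjusted p = 0.174). Cd8a had a log2 fold change of -0.62 and Itgae of 0.94 (adjusted p = 0.0809 for both).

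Lists that did not pass between the double knockouts were cDC2 (1 rose when adjusted over the list alone, median -0.13, adjusted p = 0.0902; 0.0375, 0.0127 and 0.0238, lower, without Zeb2 KO replicate 3, Nfil3 Zeb2 DKO replicate 2 or Zeb2 Id2 DKO replicate 2), E and ID proteins other than Id2 (0 of 6 called; -0.01, adjusted p = 0.931) and red pulp macrophage (2 fell when adjusted over the list alone, -0.14, adjusted p = 0.0902). That list's adjusted p was 0.0375 and 0.0238, lower, without Zeb2 KO replicate 3 or Zeb2 Id2 DKO replicate 2. B cell genes (0.30, adjusted p = 0.0825; 0.0106, higher, without WT replicate 1), cell cycle genes (-0.14, adjusted p = 0.271; 0.0340, lower, without Nfil3 Zeb2 DKO replicate 1), immediate early genes (median 0.11, mean -0.02, camera direction up, adjusted p = 0.197; 0.0161, higher, without Zeb2 Id2 DKO replicate 1) and Toll-like receptor genes (3 rose when adjusted over the list alone, 0.13, adjusted p = 0.110; 0.0388, higher, without Zeb2 Id2 DKO replicate 1) did not pass. Neither did MHC class I (0.00, adjusted p = 0.473) and MHC class II genes (1 fell when adjusted over the list alone, -0.01, adjusted p = 0.406), with the MHC gene H2-Eb2 at -0.94 (adjusted p = 0.130).

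Calls were shared between comparisons that use the same arrays. All 4 genes changed in Zeb2 KO were also changed in the same direction in Zeb2 Id2 DKO against WT, 1 higher (Ngp) and 3 lower (Rtn1, Zfyve9 and Cd80), against 0.00878 and 0.0167 expected for independent comparisons. In 100 simulations without effects, the same numbers of genes with the smallest p shared 0.53 and 1.44 on average (up to 1 and 3). Of the Zeb2 Id2 DKO genes against WT, 64 higher and 24 lower ones were shared with the comparison to Zeb2 KO (0.641 and 0.145 expected, 26.0 and 10.8 simulated) and 93 and 33 with the comparison to Nfil3 Zeb2 DKO (1.02 and 0.234 expected, 31.0 and 12.3 simulated). The latter 2 comparisons shared 53 and 20 (0.425 and 0.0548 expected, 18.1 and 5.75 simulated). Part of the excess may come from the shared arrays, as too few WT, Zeb2 KO or Zeb2 Id2 DKO arrays exist to split them into groups of at least 2.

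Effects of the further Nfil3 and Id2 losses, both against Zeb2 KO, had a correlation of 0.128 (covariance 0.00426) across 19938 genes. In 100 simulations with the same spread in every array, the shared Zeb2 KO arrays gave 0.400 (0.356 to 0.451). Deviations from genotype means had standard deviations of 0.142 to 0.220 in Zeb2 KO and 0.081 to 0.084 in the double knockouts. The simulations therefore decide nothing. Without Zeb2 KO replicate 1, 2 or 3 the correlation was 0.304, 0.335 or 0.231 (simulated 0.499 to 0.501). The covariance was then 0.0123, 0.0145 or 0.00863. Without Zeb2 Id2 DKO replicate 1 the correlation was 0.0768. No gene was called in both. Against WT the correlation was 0.242 and the covariance 0.00810. Genes are not independent replicates, so these values describe the arrays and carry no p-value.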

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

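None of the tests in this part was chosen after its result was seen. Probe sets that name no gene or several genes, 7064 in all, stand outside the gene-level comparisons, and this is why they are given here: tested in the same way, 2 changed between Zeb2 KO and WT, 49 between Zeb2 Id2 DKO and WT (34 higher and 15 lower), and 1 between Nfil3 Zeb2 DKO and Zeb2 KO. Between Zeb2 Id2 DKO and Zeb2 KO 26 changed (25 higher and 1 lower), and between Zeb2 Id2 DKO and Nfil3 Zeb2 DKO 32 changed (25 higher and 7 lower). What these probe sets measure was not analysed here.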

How the results depend on the processing

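Removal of both WT replicate 1 (B cell transcripts higher) and Zeb2 KO replicate 3 (lowest correlation with its group) and of targeted genes from lists was chosen only after the data were seen, and the other tests in this part were set before. Every count of changed genes moved with the arrays used. Of 110 calls of named genes (once per comparison), 43 were kept in every alternative but treat and every probe set, run for counts only. Removal of dim genes took out Ifit1 and Lrrc4c, among the 43. The other 67 were lost in at least 1, and 0 turned direction. Causes were not tested call by call. The estimated correlation ended 52 list calls and fry 39. Without targeted genes 1 list call ended, E and ID proteins between Zeb2 Id2 DKO and WT (adjusted p = 0.670).

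Counts of changed genes moved as follows. Zeb2 KO against WT (4): 0 with each array shifted to the same median, 2 with robust eBayes, 75 with array weights, 1 with only the 2 groups compared, 0 with treat, 500 without both arrays, 0 to 165 with each array left out. Nfil3 Zeb2 DKO against WT (1): 23 with array weights, 2 with only the 2 groups compared, 62 without both arrays, 1 to 7 with each array left out. Zeb2 Id2 DKO against WT (286): 1076 with array weights, 554 with only the 2 groups compared, 74 with treat, 1104 without both arrays, 67 to 760 with each array left out. Nfil3 Zeb2 DKO against Zeb2 KO (1): 2 with every probe set, 4 with array weights, 266 without both arrays, 1 to 106 with each array left out. Zeb2 Id2 DKO against Zeb2 KO (99): 256 with array weights, 20 with only the 2 groups compared, 26 with treat, 245 without both arrays, 25 to 148 with each array left out. Zeb2 Id2 DKO against Nfil3 Zeb2 DKO (158): 1139 with array weights, 833 with only the 2 groups compared, 47 with treat, 958 without both arrays, 23 to 704 with each array left out. All 286 stayed called with array weights, without both arrays, and without Zeb2 KO replicate 3. That array lowered the 286 and 158 through the variance alone, being in neither comparison. The correlation of the effects of the 2 further losses was 0.242 against WT and 0.077 to 0.335 with each array left out.

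With replicate number as a block, 8 genes changed in Zeb2 KO and 183 in Zeb2 Id2 DKO against WT, 171 of the latter shared with the 286. The labels do not say that numbers pair the arrays. Correlations of deviations from genotype means were 0.04, -0.31 and -0.02 between WT and Zeb2 KO arrays of the same number. Other pairs of the same number had -0.13 to 0.16. Not every array's deviations correlated best with those of its own number. In genotypes with 2 arrays the deviations of both arrays mirror each other, so their correlations with another array differ only in sign. Under this block the cell cycle list turned direction between Nfil3 Zeb2 DKO and Zeb2 KO (adjusted p = 0.00591).

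Other lists turned direction while passing neither with all arrays nor in the alternative. Those that passed in at least 1 of the 2, with their adjusted p in the alternative, were B cell between Zeb2 KO and WT (0.0612 without both arrays, 5.28e-09 to 0.762 with each array left out, the latter without WT replicate 1) and between Zeb2 Id2 DKO and WT (0.0430 without both arrays). Cell cycle did so between Zeb2 KO and WT (9.71e-11 without both arrays, 0.0232 without WT replicate 1, 0.0297 without Zeb2 KO replicate 3; 0.00303 to 0.322 with each array left out), between Nfil3 Zeb2 DKO and WT (0.00311 without both arrays, 0.0128 without WT replicate 1; 0.00399 to 0.617 with each array left out) and between Nfil3 Zeb2 DKO and Zeb2 KO (6.04e-05 without both arrays, 0.0143 without Zeb2 KO replicate 3; 0.0143 to 0.953 with each array left out). Further lists were dendritic cell maturation between Nfil3 Zeb2 DKO and WT (2.76e-07 to 0.642 with each array left out, the latter without Nfil3 Zeb2 DKO replicate 2) and neutrophil between Zeb2 Id2 DKO and Zeb2 KO (0.000395 without Zeb2 Id2 DKO replicate 1; 3.67e-07 to 0.520 with each array left out). Fry, which tests a list against no change and not against other genes, gave cDC1 identity as lower between Zeb2 Id2 DKO and Nfil3 Zeb2 DKO (0.0496). Without the targeted Id2 it did not (0.405, higher).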

Other observations

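Among the tests in this part, only the splits of the WT and Zeb2 KO arrays were written down before their result, and all others were chosen only after the result was seen. In WT, Nfil3 and Id2 lay at percentiles 96.0 and 95.3 of all genes, and Siglech and Spib at 46.6 and 43.7.

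Neutrophil genes higher in the arrays labelled Zeb2 KO and Zeb2 Id2 DKO may come from neutrophils or their precursors among the sorted cells. Members varied together between arrays of a genotype (median pairwise correlation 0.721 over 136 pairs, reached by 0 of 10000 random lists, of which the highest had 0.464). This is what the hypothesis, found and tested on the same arrays, predicted. Genes that are regulated together would also exceed random lists if cDC1s expressed them, so the test cannot tell the sources apart. Cells were sorted as cDC1s by a gate that is not given; in WT the most abundant members were Il1b (11.1 to 11.3 log2), which cDC1s also express, and Ngp (8.4 to 8.7), no other of the 17 exceeded 8.3, and none stands in another list. The array that stands apart, Zeb2 KO replicate 3, could not account for the pattern, as the median log2 change without it was 1.41 against 1.26. Expression of these genes by cDC1s themselves was not tested.

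Interferon-stimulated genes and Siglech, Cd300c and Bst2 were higher in the Zeb2 Id2 DKO arrays, and 1 array alone is unlikely to be the source, as both arrays lay above all 8 others in 20 of 25 members (5.01% of all genes did so). A local effect of the targeted Id2 locus on its neighbours would reach only Rsad2 and Cmpk2, and the other 23 members had a median log2 change of 0.93 against Zeb2 KO. Plasmacytoid dendritic cells among the sorted cells cannot be told apart from expression by cDC1s. The 12 pDC members no higher than Siglech in WT had a median change of 0.11 (upper quartile 0.33, highest after Siglech 0.60). But some lay low in WT (down to 4.04 log2), and the whole pDC list was higher. Cells were sorted as cDC1s by a gate that is not given, the other 18 of 30 pDC genes lay above Siglech in WT, led by Bst2 (10.45 to 10.78 log2), and 7 stand in other lists, Bst2 among the interferon-stimulated genes.

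Auh, which lies next to Nfil3 on the chromosome, stood 1.56 log2 higher in the Nfil3 Zeb2 DKO arrays than in Zeb2 KO. An effect of the targeted Nfil3 locus on the gene next to it and a wider stretch around Nfil3 that differs between the strains cannot be told apart. That 0.0301% of 19917 genes have an immediate neighbour with a p as small follows from the rank of Auh by p (3) and decides nothing, and the neighbour on the other side, Ror2, had a log2 change of -0.01. Among 19 further genes near Nfil3, 4 had an unadjusted p under 0.05 (Sema4d, Sfxn1, Hrh2 and Simc1), against a median of 2, and 8.96% of stretches held as many.

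In the number of genes changed between Zeb2 KO and WT, 2 of 10 splits of the 6 arrays into 3 and 3 gave as many genes, the real split with 4 included. The highest other split, WT replicate 1 with Zeb2 KO replicates 1 and 2 against the rest, gave 112. The 10 splits are too few for a share under 0.05, and a split that calls many more genes points to a structure of the samples, here the arrays WT replicate 1 and Zeb2 KO replicate 3.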
